A study of Synechocystis sp. PCC 6803 with 72 samples.

How the data were processed

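RNA of Synechocystis sp. PCC 6803 was measured in 72 libraries from 6 continuous cultures, 3 control and 3 heated, at 12 hourly time points. Per the labels' protocols the cultures grew in buffered BG-11 medium with air enriched to 1% CO2 under continuous light of 150 µmol photons. RNA was extracted with Tri-Reagent and DNase, libraries were made with a stranded mRNA kit (TruSeq), and adapters and low-quality bases were removed from the reads. Each deposited file holds whole-number counts of reads per gene for 1 library, not normalized. The submitters' processing notes list TopHat2 2.1.2, Bowtie2 2.3.4.1, Picard and HTSeq. The genome build, the annotation, the strand setting of the counting and the role of each tool are not given in the sources used here. A kit that keeps the strand can be counted on either strand, so it is open whether a gene's counts are reads of its own strand or of the other.

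Each file lists 3558 genes and 5 tally lines, which were kept out of library sizes and tests. Of the uniquely aligned reads 86.2 to 95.6% per library fell on no gene, at most 0.425% were ambiguous between genes, and 4.27 to 13.3% (median 8.39%) were assigned to a gene. Alignments that were not unique made up 16.7 to 72.2% of alignments and entered no gene's count, so close copies of a gene may have lost reads. How many reads each gene lost is not known. Values of gene families, such as psbA2 and psbA3 or symbols ending in _1, _2 and so on, are therefore uncertain. Depth ran from 7939 to 610298 gene counts per library. Depth was lower in the control arm: 18 control and 2 heated libraries held fewer than 60000 counts, and 14 and 30 held at least 100000. Of the 72 pairs of libraries of the same arm and time point the smallest ratio of chi-square to degrees of freedom was 1.72, so no pair agreed within sampling noise and none was merged.

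Groups, culture numbers and time points came from the labels. The tests, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Heated and control cultures were compared at each time point with edgeR 4.0.16 (R 4.3.3) on the 6 libraries of that time point: TMM normalization, filterByExpr with a minimum count of 10, robust quasi-likelihood fit and F test, and Benjamini-Hochberg adjustment over the genes tested, called at an adjusted p under 0.05. Time points 0, 3, 6, 9 and 11 were the planned comparisons and the other 7 a profile. The trajectory test took the 11 arm-by-time terms together over all 72 libraries, with culture as a replicate block and time point as covariates. Change over time was tested in each arm over its 36 libraries with culture as a replicate block. Means and SDs of CPM, which use totals over the tested genes scaled by TMM within the time point, are over the 3 cultures of an arm, the courses figure shows CPM from plain totals, and fold changes are heated over control, or time point 11 over 0.

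The 29 gene lists were tested at time points 3, 6, 9 and 11 with limma 3.58.1 (voom, camera with a preset correlation of 0.01, lists of at least 3 measured members), and their members were counted among edgeR's calls. Of 349 list genes 339 were matched to names in the files, 49 by locus tag, 202 by the same symbol and 88 by a family or older symbol. For the last kind the file's symbol is printed, and which member of the family it is remains uncertain. Of the 3558 names 379 were symbols in the RefSeq table of assembly GCF_000284455.1, which was used for names only, and no coordinates are given because the build of the counts is open.

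Genes named for a comparison had an adjusted p under 0.05, a mean of at least 50 counts over the 6 libraries and no overlap between arms: the 12 largest changes up and 12 down at time point 11, 4 and 4 at time points 3, 6 and 9, and 3 and 3 at time point 0. For the tests over time the 3 smallest p were taken, and any list member could be named with its value. The result of 1 list member is not reported here. Genes that illustrate depth and ranks were chosen after their values were seen.

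Alternatives fixed at that time were DESeq2 1.42.0 in place of edgeR, DESeq2's size factors in place of TMM, no low-count filter, the label number as a replicate block, a single fit of all 72 libraries in edgeR and in limma voom with culture as a random effect, each culture left out, the change from time point 0, no replicate block, slopes per culture, an estimated correlation in camera, and fry. Chosen after seeing the data were fits without libraries under 60000 counts, without the 268 background genes, with the controls of a time point replaced by the sum of each control culture's libraries of at least 100000 counts, and of the heated cultures against themselves at time point 0. The fits were tested on simulated counts with real means and library sizes, in which 100 genes changed 2-fold and 100 changed 4-fold. For the tests over time the change was present in full from time point 6 to 11, not gradual. At time point 11 the test found 35% of the first and 86% of the second with 1 false call, at time point 3 12% and 74% (5 false calls), at time point 6 29% and 86% (5), at time point 9 41% and 91% (8), and at time point 0 34% and 86% (6). The trajectory test found 20% and 83% (4 false calls), and the test over time 85% and 95% (7) in heated and 44% and 87% (4) in control cultures. Figures were drawn with matplotlib 3.10.9 (Python 3.11.15).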

Results

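The series followed the cyanobacterium Synechocystis sp. PCC 6803, a freshwater bacterium that photosynthesises as plants do, through a gradual heat stress, and the comparisons below ask how its transcripts changed as the cultures warmed. The 6 continuous cultures (control cultures 2, 3 and 4 and heated cultures 1, 2 and 3, as the labels number them) had been held at 30 °C. Each was sampled at 12 hourly time points, 0 to 11, which gave 72 libraries. The labels give no temperature for the heated time points, so time since the first sampling stands for the course of heating. The labels call the cultures biological replicates, so the p-values of a single time point measure the spread between separate cultures, 3 per arm. The tests over time remove each culture's own level and then treat its hourly libraries as independent. Their p-values measure scatter within cultures, and with 1 slope per culture the trajectory test called 23 genes in place of 167.

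Between 7939 and 610298 reads per library were counted on the 3558 genes, with a median of 66472 in the 36 control libraries and 239522 in the 36 heated ones. Of the control libraries 18 held fewer than 60000 gene counts, against 2 of the heated libraries. Genes received 4.27 to 13.3% of the uniquely aligned reads of a library. The strand setting of the counting is not given in the sources used here, and the libraries were made with a stranded kit. Each value below is the abundance of reads assigned to a gene's name, on whichever strand they were counted. The genes of abundant proteins that were looked up had ranks from percentile 33.6 (psbD) to 78.4 (cpcA). Over the 44 libraries of at least 100000 counts, psbA2, which codes for the D1 protein of photosystem II, stood at percentile 35.1 of all genes, cpcB of the phycocyanin antenna at 48.8 and tufA, the elongation factor Tu gene, at 35.4. The phycocyanin gene cpcA stood at 78.4, the Rubisco gene rbcL at 77.1, the photosystem I genes psaA and psaB at 75.1 and 74.6, and the allophycocyanin gene apcA at 64.4. The others looked up were psbD2 at 34.1, apcB at 38.1, rbcS at 47.7, petE at 54.3 and psbA3 at 56.0.

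A set of 268 genes, called background genes here, held a share of the counts that was at least 2 times higher in the pooled control libraries under 60000 counts than in those of at least 100000. They made up a median of 41.7% of the counts in the 18 shallow control libraries (20.8 to 62.8%), 9.26% in the 14 deep control libraries (5.73 to 18.1%) and 9.62% in the 36 heated libraries (6.18 to 21.2%). The gene thrC_1 had a median of 992 counts in the shallow control libraries and 990 in the deep ones, which was 3.79% and 0.459% of the pooled counts. Because they moved with the depth of the control arm, the number of calls that fall on these genes is given beside the count of each comparison.

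**Figure D1:**
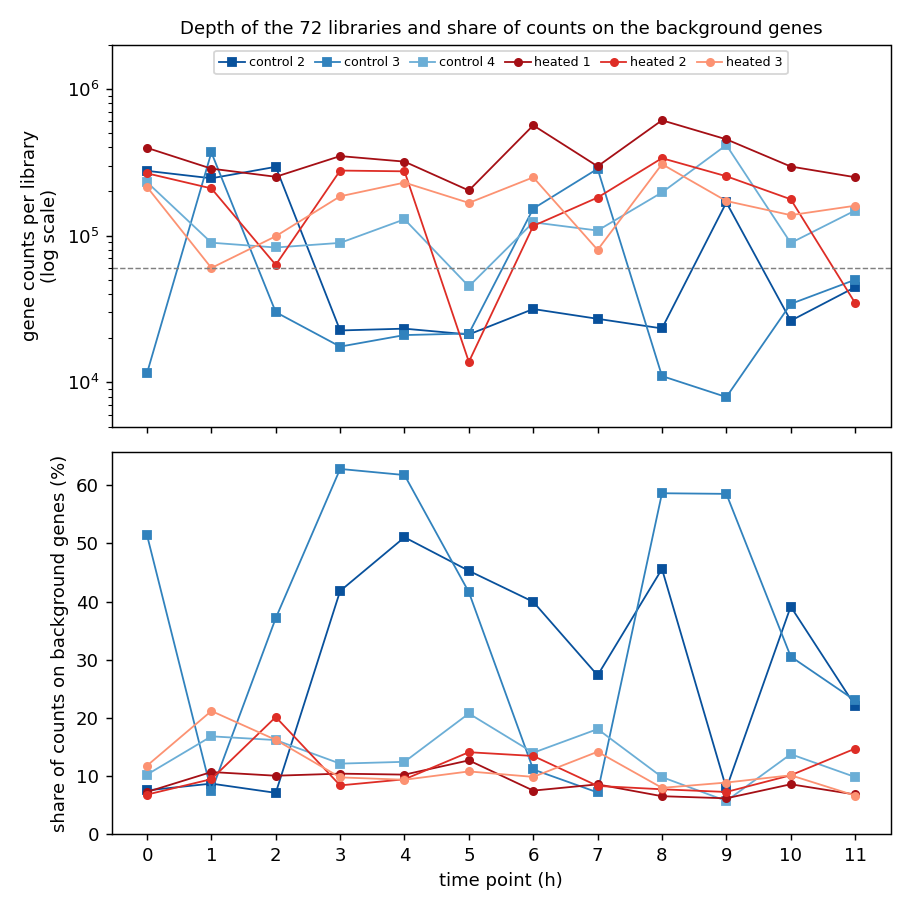
Gene counts per library (upper panel, log scale, dashed line at 60000 counts) and the percent of those counts on the 268 background genes (lower panel) at each hourly time point, with one line per culture. Shallow libraries of control cultures 2 and 3 held up to 62.8% of their counts on these genes, and no heated library exceeded 21.2%.

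At time point 0, the first sampling, no gene passed the test between the cultures assigned to heat and the control cultures. edgeR's quasi-likelihood test called 0 of 2731 genes, and DESeq2 and limma voom also called 0. In edgeR's test 36 genes had an unadjusted p under 0.05, fewer than chance alone would give. With control culture 2 left out, the 2 remaining controls included a library of 11552 counts and the test called 32 genes.

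At time point 11 the locus slr1597 showed the largest increase among the genes that the naming rule admits. It stood at 51.2 ± 16.8 CPM (counts scaled to a library's total over the tested genes, with TMM normalization) in the control cultures and 2431 ± 1190 in the heated ones (SD, n = 3 each), a log2 fold change of 5.72 (SE 0.47). The gene aspC, for an aspartate aminotransferase that moves amino groups between aspartate and glutamate, stood at 905 ± 70.3 CPM in the control and 5612 ± 847 CPM in the heated cultures (log2 2.63, SE 0.34). The gene livG, for the ATP-binding part of a transporter of branched-chain amino acids, stood at 471 ± 104 and 2608 ± 318 CPM (log2 2.45, SE 0.32). Among loci known by their tags, slr0320 stood at 136 ± 10.1 and 1528 ± 657 CPM. The locus sll1620 was higher by 3.22 on the log2 scale, sll8025 by 3.22, sll1634 by 3.01, slr0544 by 2.85, slr0073 by 2.82, slr1113 by 2.82, ssl2971 by 2.65 and slr0964 by 2.63. Their standard errors ran from 0.33 (sll1634) to 0.53 (slr1113).

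Of the genes that were lower at time point 11, sucC, for a subunit of succinyl-CoA synthetase in central carbon metabolism, stood at 1797 ± 505 CPM in the control cultures and 162 ± 62.0 in the heated ones (SD, n = 3 each; log2 −3.33, SE 0.34). The gene codA, for cytosine deaminase of pyrimidine salvage, stood at 4281 ± 1421 and 499 ± 217 CPM (log2 −3.01, SE 0.37), and sll1934 at 3255 ± 1491 and 369 ± 36.5 CPM (log2 −3.16, SE 0.36). The lipoprotein gene rlpA (log2 −2.37, SE 0.39) and ndhD_2 (−2.12, SE 0.31), for a subunit of the NDH-1 complex that passes electrons to plastoquinone, were lower too. The other 7 genes that the rule admits were background genes: slr7068 (log2 −4.19), ssr1038 (−4.00), slr0881 (−3.66), gshB for glutathione synthetase (−3.31), sll1071 (−3.25), gcp (−3.21) and slr0624 (−2.34). All 24 genes separated the 3 heated from the 3 control cultures with no overlap, as the rule requires, and their adjusted p-values from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment ran from 2.72e-09 (slr1597) to 0.0247 (ssr1038).

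In all, edgeR called 532 of the 2045 genes tested at time point 11, 269 higher and 263 lower in the heated cultures, and 53 of the lower ones were background genes. Over all genes tested the groups did not overlap for 821, or 40.1%, against 222 of 2731 (8.13%) at time point 0, where chance separates 10%. The share was also 24.5% at time point 3, where all 38 calls were background genes, and 23.6% at time point 6, with 2 calls. Separation above chance therefore does not by itself measure an effect of heating. With heated culture 1 left out the count of calls was 274. It was 170 with the label number as a replicate block, a fit that compares only cultures 2 and 3 of each arm. For the change from time point 0 with culture as a replicate block it was 232. Against summed deep controls, a fit chosen after the result was seen, it was 1254. The 17 named genes outside the background set were called under each of 17 alternatives, and 0 of the 7 background genes were called under all of theirs. Over their alternatives the weakest log2 values of the 7 were −2.43 for slr7068, −2.04 for slr0881 and −1.55 for ssr1038 and for gshB. They were −1.37 for gcp, −1.21 for sll1071 and −1.09 for slr0624.

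The phycobilisome list, whose genes build the light-harvesting antenna, had 4 of its 8 measured members higher at time point 11 (5 adjusted over the list alone), none lower and 4 that did not pass. The allophycocyanin gene apcB was higher by 2.39 on the log2 scale (SE 0.49), the phycocyanin genes cpcA by 2.29 (SE 0.33) and cpcB by 2.15 (SE 0.46). The linker gene apcC stood at 68.1 ± 52.7 CPM in the control and 243 ± 141 in the heated cultures (SD, n = 3 each). cpcA stood at 364 ± 119 CPM in the control and 1707 ± 275 in the heated cultures (SD, n = 3 each). apcC was not called without control culture 3 (log2 1.41) or heated culture 2 (1.32), and the low-count filter kept it out of 3 of the 6 fits that left out a culture. The list had a median log2 fold change of 1.39, and limma camera gave it an adjusted p = 0.135, so the list as a whole did not pass. It had an adjusted p = 0.926 with an estimated correlation. The filter kept only these 8 of the list's 14 members. Over the 13 measured within the heated cultures the median change from time point 0 to 11 was 0.55.

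Genes of the photosystems moved in both directions. In photosystem I, psaB (log2 1.87, SE 0.35) and psaA (1.22, SE 0.32), which code for the core proteins that hold the reaction centre, were higher and the small-subunit gene psaJ (−1.98, SE 0.63) was lower, with 4 of 7 members not passing. In photosystem II, psbZ (1.86, SE 0.55) was higher, psbM (−2.52, SE 0.63) and the background gene psbT (−1.77, SE 0.56) were lower, and 9 of 12 did not pass. psaA was not called without heated culture 1 (1.04), psbZ (1.61) and psaJ (−1.67) without control culture 3, and psbT without control culture 3 (−1.26) or heated culture 1. Against summed deep controls, a fit chosen after the result was seen, psbT had a log2 fold change of −0.22 and was not called. The filter kept psaJ and psbM out of 3 of the 6 fits that left out a culture and psbZ out of 1, and psbM was called in the 3 that tested it. Of the cytochrome b6f and electron carrier genes 1 of 6 was lower (3 adjusted over the list alone), petH for ferredoxin-NADP reductase (−1.45, SE 0.33), and the median was −0.95. The filter kept only these 6 of the list's 14 members. Over all 14 the median change from time point 0 to 11 within the heated cultures was 0.53, with 1 member higher and 3 lower. The NDH-1 gene ndhB was higher (1.31, SE 0.34) among 7 measured members of that core. The ATP synthase gene atpB was lower (−1.24, SE 0.40; lost without control culture 4 or heated culture 1 or 3) among 5. The gene hoxH, the 1 measured hydrogenase gene, was higher, at 330 ± 78.2 CPM in the heated and 71.8 ± 21.5 in the control cultures (SD, n = 3 each).

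**Figure D2:**
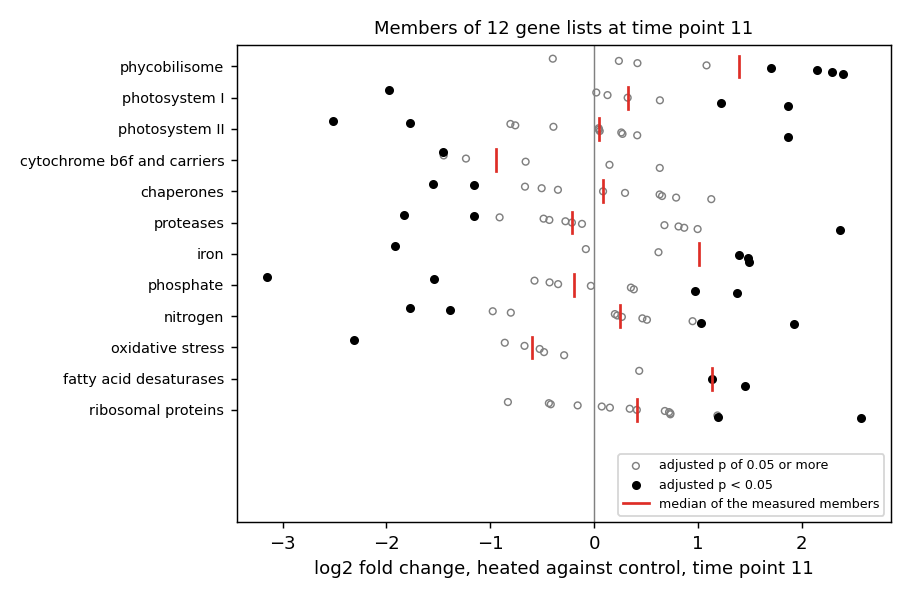
Log2 fold change of heated against control cultures at time point 11 (x axis) for each measured member of 12 gene lists (y axis). Filled points had an adjusted p under 0.05 in edgeR's test over all genes, open points did not, and red lines mark list medians, 1.39 for the phycobilisome and −0.95 for cytochrome b6f and carriers.

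Heat-shock genes differed in coverage. hsp17, for the small heat-shock protein, had 0 to 10 counts and groES 0 to 6 counts per library at time point 11, too few to be tested, while htpG had 15 to 146, clpB 21 to 149 and dnaK_2 6 to 104. Of the 11 chaperone genes that could be tested, groEL (log2 −1.16, SE 0.43) and the background gene dnaJ_1 (−1.56, SE 0.45) were lower, none was higher and 9 did not pass (0 higher and 1 lower adjusted over the list alone). htpG, an HSP90-type chaperone gene, had a log2 fold change of 0.65 with an edgeR adjusted p of 0.132. groEL lost its call in 5 of the 6 fits that left out a culture, and dnaJ_1 in 3 of them. Against summed deep controls dnaJ_1 had a log2 fold change of −0.71 and was not called. The regulator gene slr0947 (rpaB) was higher (1.71, SE 0.41) among 3 measured regulators. The sigma factor gene rpoD was lower (−1.24, SE 0.41) among 5 (1 higher and 1 lower adjusted over the list alone), but lost its call without control culture 3 or 4 or heated culture 1 or 3. Among 13 protease genes, clpP_1 of the Clp protease was higher (2.37, SE 0.57), the background gene ftsH (−1.84, SE 0.32) and prc (−1.16, SE 0.30), for a carboxyl-terminal processing protease, were lower, and 10 did not pass. Without control culture 4 clpP_1 fell to 1.56 and lost its call.

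Nutrient and stress lists held calls in both directions at time point 11. In the iron list slr0513 (futA2; 1.49, SE 0.37) and the ferrous iron transporter gene feoB (879 ± 189 CPM heated, 320 ± 103 control; SD, n = 3 each) were higher. Of the bacterioferritin genes, which code for iron storage proteins, bfr_1 was higher (1.48, SE 0.37) and bfr lower (−1.92, SE 0.40), with 2 of 6 not passing. Among 12 nitrogen genes, the nitrate and nitrite reductase genes narB (−1.77, SE 0.46) and nirA (−1.39, SE 0.40) were lower, and nblA (1.92, SE 0.58), needed for phycobilisome breakdown, and gltS (1.03, SE 0.29) were higher. With a culture left out, nirA lost its call without heated culture 1 or 3, gltS without control culture 3 and nblA without control culture 3 or 4. narB was called in the 5 fits that tested it. Among 10 phosphate genes, pstS (−1.54, SE 0.37) and the background gene pstB (−3.15, SE 0.55) were lower and sphX (1.38, SE 0.52) and pstC (0.98, SE 0.37) higher. The last lost its call in all 6 of those fits and sphX in 5, and without control culture 4 sphX fell to 0.78. slr1738, the gene of the peroxide-responsive repressor PerR, was lower (−2.31, SE 0.38) and the other 5 oxidative stress genes did not pass.

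Membrane, pigment and carbon lists also held calls. The fatty acid desaturase genes desC(des9) (1.45, SE 0.35) and desA (1.14, SE 0.41) were higher among 3 measured, and desA lost its call in 4 of the 6 fits that left out a culture. Of 7 photoprotection genes (2 higher and 2 lower adjusted over the list alone) sll0217 (flv4) was higher (1.23, SE 0.35), ssl1633 (hliC; −2.15, SE 0.41) and isiA (−1.09, SE 0.33) lower, with sll0217 lost without heated culture 1, and isiA without that culture or control culture 4. In chlorophyll and haem synthesis hemA (1.67, SE 0.45) and sll1214 (1.01, SE 0.35) were higher, chlG (−1.21, SE 0.34) and hemN (−0.94, SE 0.35) lower and 7 of 11 did not pass. Both sll1214 and hemN lost their call in 5 of those fits, and without control culture 4 hemN stood at −0.59. prk, for the Calvin cycle enzyme phosphoribulokinase, was higher (1.75, SE 0.42) and the carboxysome shell gene ccmK lower (−0.97, SE 0.35, lost in 4 of those fits), with 10 of 12 members not passing (1 higher and 0 lower adjusted over the list alone). The oxidase gene ctaE_1 was higher (2.31, SE 0.54), the other 5 terminal oxidase genes did not pass, and slr0531 (ggtD) of glucosylglycerol transport was lower (−1.55, SE 0.29). slr0529 (ggtB) of the same transport was higher (1.52, SE 0.54) but lost its call without control culture 3 or 4. Among 15 glycogen and sugar genes glgA_1 was higher (1.22, SE 0.40) and gap1 lower (−0.81, SE 0.30), each lost in 4 of those fits, and neither passed adjusted over the list alone.

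Of 15 ribosomal protein genes measured at time point 11, rps18 was higher (2.57, SE 0.56) and 13 did not pass. rps18 was called in the 4 fits with a culture left out that tested it. No member was called in the lists for inorganic carbon uptake (6 measured), RNA polymerase (5), carotenoids (4; 1 higher and 1 lower adjusted over the list alone), pili (3), the circadian clock (3) or cold-inducible genes (1). Over all 29 lists 29 of 208 measured members were higher and 23 lower (32 and 23 adjusted over the list alone, list by list). Among all 2045 genes tested 269 were higher and 263 lower, so list members were called about as often as any gene. All 52 called list members kept their direction with DESeq2's size factors, and in every fit with a culture left out that tested them. They were chosen as called in the same libraries, 49 of them with no overlap between the arms, so a change of direction was hardly possible. Of the 52, 27 were called in each of the fits that tested them and 25 were not called in at least 1. Against summed deep controls all 52 kept their direction and 50 were called, all but psbT and dnaJ_1. As whole lists 0 of 27 passed limma camera, 3 with an unadjusted p under 0.05, and none passed with an estimated correlation. Limma fry called 2, the phycobilisome list upward (adjusted p = 0.0176) and the cytochrome b6f and carriers list downward (adjusted p = 0.00345). The downward call covers 6 of that list's 14 members, and over all 14 the median change within the heated cultures was upward (0.53). The phycobilisome call covers 8 of 14 members, and over the 13 measured within the heated cultures the median change was 0.55.

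At time point 3 the calls were all in 1 direction and all on background genes. The genes ssr6099 (log2 −3.68, SE 0.82), ssr1038 (−3.59, SE 0.82), slr1978 (−3.58, SE 0.63) and sll0827 (−3.57, SE 0.72) were lower in the heated cultures, with edgeR adjusted p-values of 0.0196 (slr1978) to 0.0360 and no overlap between the arms. Each kept its call in 5 or 6 of 16 alternatives. ssr6099 stood at 568 ± 161 CPM in the heated cultures and 7409 ± 6031 in the control cultures (SD, n = 3 each), where 2 of the 3 libraries were shallow. edgeR called 0 of 2282 genes higher and 38 lower, and all 38 were background genes. Set against their own time point 0 the heated cultures gave log2 values of 0.18 for ssr6099, 0.62 for ssr1038, 0.15 for slr1978 and −0.03 for sll0827. That fit called 4 genes, 0 of them among the 38. With any 1 heated culture or control culture 2 left out the count was 0, without control culture 3 it was 5, and without control culture 4 it was 357. Of 229 measured list members 4 were lower (dnaJ_1, ssl2982, nrtB and pstB, all background genes) and none higher (9 and 2 adjusted over the list alone). Limma camera passed 0 lists, 2 with an unadjusted p under 0.05, and camera with an estimated correlation and fry also passed 0.

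At time point 6 edgeR called 2 of 2318 genes. slr0300 was higher, at 1131 ± 255 CPM in the heated against 320 ± 27.2 in the control cultures (SD, n = 3 each; log2 1.85, SE 0.29). The cytosine deaminase gene codA was lower, at 1239 ± 126 against 5866 ± 1863 CPM (log2 −2.24, SE 0.35). Both had an edgeR adjusted p of 0.0268 and separated the arms in 6 of 6 cultures, and of 17 alternatives slr0300 kept its call in 10 and codA in 11. Without control culture 2 the count was 112, and with any other single culture left out it was 0. No list member passed (7 higher and 3 lower of 238 adjusted over the list alone), and 0 lists passed limma camera, 1 with an unadjusted p under 0.05, or passed with an estimated correlation or fry.

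At time point 9 slr1597 was already 3.09 higher on the log2 scale (SE 0.43; 436 ± 350 against 80.0 ± 51.2 CPM, SD, n = 3 each), beside ski2 (2.98, SE 0.58), slr0462 (2.59, SE 0.40) and sll0939 (2.54, SE 0.68). codA (log2 −2.39, SE 0.55) and the background genes slr7068 (−3.92, SE 0.80), slr0881 (−3.80, SE 0.69) and slr2031 (−3.22, SE 0.76) were lower. These 8 genes separated the arms with no overlap, and their edgeR adjusted p-values ran from 6.07e-09 (slr1597) to 0.00486 (sll0939). None kept its call in all alternatives: ski2 and slr0462 did in 16 of 17, slr1597 and codA in 14, sll0939 in 11, slr0881 in 12 of 16, slr7068 in 11 of 16 and slr2031 in 10 of 15. The weakest log2 values of the background genes over their alternatives were −1.64 for slr7068, −1.68 for slr0881 and −0.81 for slr2031. Of 277 measured list members 11 were higher and 10 lower (19 and 21 adjusted over the list alone). Among the higher were apcB (1.97, SE 0.47), clpP_1 (1.77, SE 0.43), desA (1.67, SE 0.35) and dnaK_1 (1.31, SE 0.39), a chaperone gene. Among the lower were petE for plastocyanin (−1.75, SE 0.40), slr1738 (−1.56, SE 0.33) and pstS (−1.55, SE 0.34). edgeR called 241 of 2691 genes, 125 higher and 116 lower, and 2 of the higher and 17 of the lower were background genes. DESeq2's Wald test called 20 genes, and without control culture 3, whose library held 7939 counts, the count was 525. With the label number as a replicate block, which compares only cultures 2 and 3 of each arm, it was 0. For the change from time point 0 with culture as a replicate block it was 18. It was 80 without control culture 2, 69 without control culture 4, 92 without heated culture 1 and 95 without heated culture 2. Limma camera passed 0 lists, 3 with an unadjusted p under 0.05, and none passed with an estimated correlation or fry.

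Fitted the same way, the other time points gave 0 calls at 1 and 2, where 70 and 17 genes had an unadjusted p under 0.05. They gave 5 higher and 84 lower (79 background genes) at time point 4, 22 and 97 (82) at 5, 14 and 11 (0) at 7, 71 and 125 (89) at 8, and 170 and 233 (105) at 10. Against each control culture's deep libraries summed over time, chosen after these counts were seen, the directions were more even, with 8 higher and 9 lower at time point 3, 119 and 152 at 4, 132 and 129 at 5, 189 and 210 at 7, 487 and 504 at 8, and 564 and 560 at 10. Of the genes higher at time point 9 and tested at both, 75 were also higher at 11, where independent lists would share 13.8, and 72 of the lower were also lower, where they would share 12.6. The libraries of these time points came from the same cultures, so the lists are not independent.

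**Figure D3:**
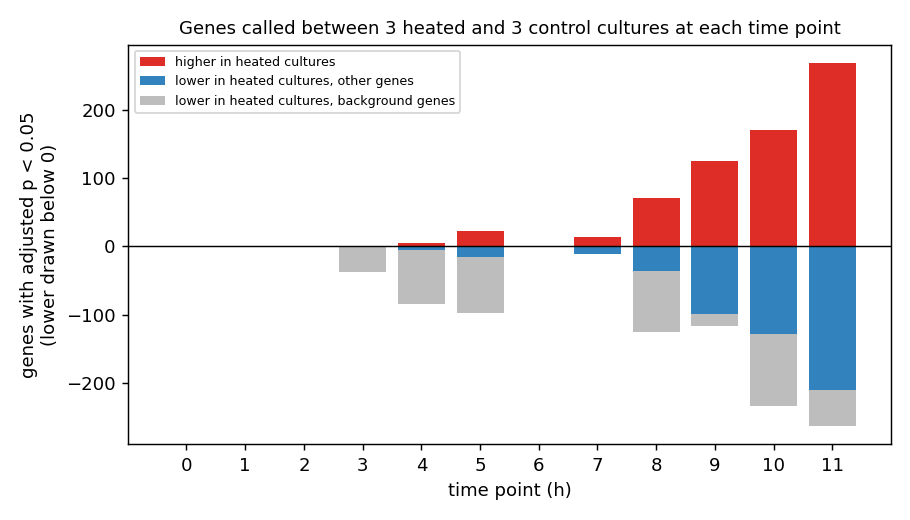
Genes called higher or lower in heated than in control cultures at each hourly time point (edgeR's quasi-likelihood test, adjusted p under 0.05, 3 cultures per arm), with the lower calls that fall on background genes drawn apart. All 38 calls at time point 3 are background genes, against 53 of the 263 lower calls at time point 11.

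Over the whole series the change of slr1597, codA and sucC differed most clearly between the arms. From time point 0 to 11 slr1597 changed by 5.59 more on the log2 scale in the heated than in the control cultures (SE 0.68), codA by −3.18 (SE 0.47) and sucC by −3.32 (SE 0.46). Their edgeR adjusted p-values for the 11 arm-by-time terms were 1.02e-13, 3.36e-10 and 4.80e-10. The test, on all 72 libraries with the culture as a replicate block, called 167 of 3044 genes, 71 of them higher and 96 lower by the last time point, and 7 were background genes. With DESeq2's size factors it called 197, 146 higher and 51 lower, and that scaling moved the median of all genes by 0.33 on the log2 scale. The count was 484 without control culture 4, 38 without heated culture 1, 33 without heated culture 2 and 55 without heated culture 3. Of the 167 genes 140 were also called at time point 11.

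Within the heated cultures aspC rose by 2.85 on the log2 scale from time point 0 to 11 (SE 0.18), codA changed by −2.89 (SE 0.22) and sll1934 by −3.25 (SE 0.22), each the same way in the 3 cultures. Their edgeR adjusted p-values over the 11 time terms, with culture as a replicate block, were 7.33e-26, 3.18e-25 and 3.35e-25. The test called 986 of 3102 genes, 470 higher and 516 lower at the last time point than at the first, 80 of them background genes, and 475 genes without heated culture 1. Taken one time point at a time against time point 0, the same fit called 0 genes at 1 and 2, 5 at 3, 17 at 4, 18 at 5, 64 at 6, 162 at 7, 389 at 8, 518 at 9, 733 at 10 and 998 at 11. At time points 1 and 2, 166 and 282 genes had an unadjusted p under 0.05.

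**Figure D4:**
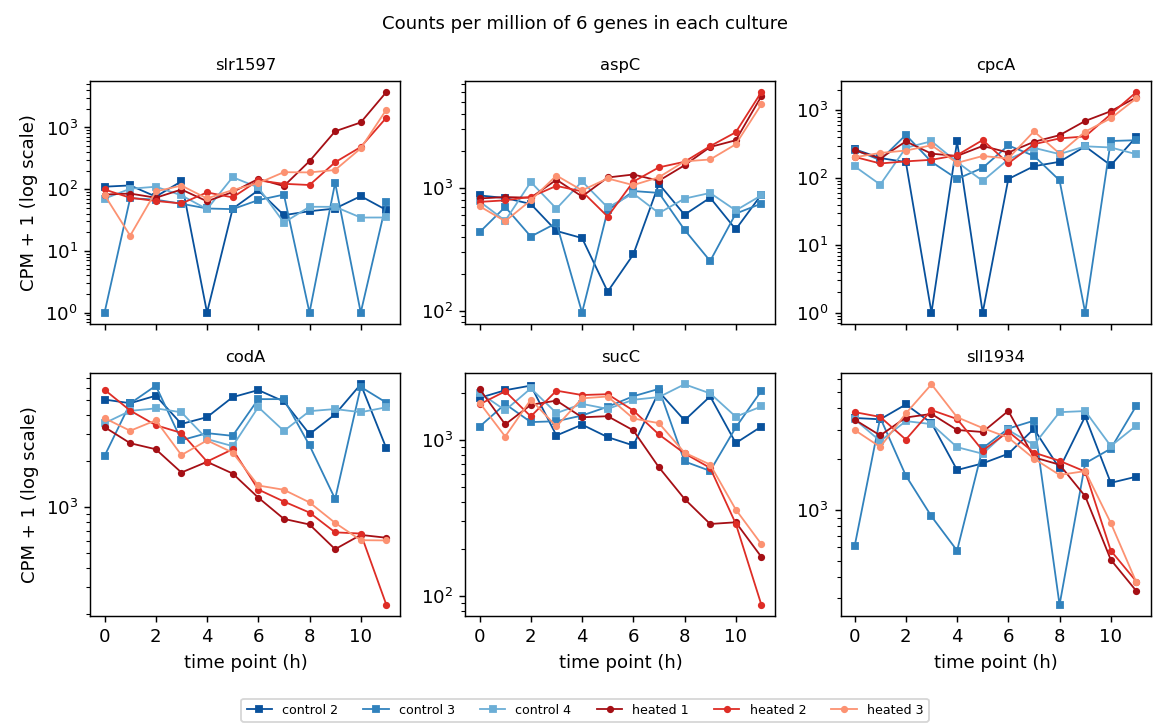
CPM from plain totals of all genes, without TMM normalization, plus 1 (y axis, log scale), of 6 genes at each hourly time point (x axis), one line per culture. slr1597, aspC and cpcA are higher, and codA, sucC and sll1934 lower, in the 3 heated than in the 3 control cultures at time point 11, and points at 1 are libraries with 0 counts of the gene.

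Of the list members measured in the heated cultures 98 of 311 changed over time by the test of the 11 time terms. Of all genes tested 986 of 3102 did, a similar share. By the separate contrast of time point 11 against 0, 61 list members were higher and 40 lower, against 505 and 493 of the 3102 genes. The phycobilisome list had 6 of 13 members higher and 2 lower, the ribosomal protein list 8 of 39 higher and 2 lower, and photosystem II 2 of 20 higher and 4 lower. Among 15 chaperone genes 2 were higher and 2 lower. Of the 532 genes called between the arms at time point 11, 527 had the same sign in this change within the heated cultures (99.1%). Simulated data with no effect gave 79.3 to 85.0%, since both comparisons use the heated libraries of time point 11.

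In the control cultures no gene passed the test of change over time. edgeR's quasi-likelihood test called 0 of 2135 genes, and DESeq2's likelihood ratio test also called 0. In edgeR's test 29 genes (1.36%) had an unadjusted p under 0.05, fewer than chance alone would give, so the test was conservative here. The same step on simulated data found 87% of genes made to change 4-fold and 44% of those changed 2-fold, 100 genes each. In the simulation those genes changed in full from time point 6 on. All libraries otherwise had the same gene shares, without the shift of background genes with depth. The absence of calls therefore does not show that the control cultures were stable.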

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

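All tests in this part were chosen after the result was seen, except the trajectory test, the splits of the samples and the shuffles of time points.

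The change over time differed between the arms, by the test of the arm-by-time terms, for 167 genes, with slr1597 (5.59 on the log2 scale from time point 0 to 11, heated minus control), codA (−3.18) and sucC (−3.32) foremost. None of the other 9 splits of the 6 cultures gave a gene (highest other 0), and 1 of 10 splits is too few for a share under 0.05. In data that no comparison used, the share of uniquely aligned reads assigned to genes was 12.6 ± 0.82% in the heated cultures at time point 11 against 8.21 ± 0.59% in the control cultures (SD, n = 3 each; two-sided exact permutation p = 0.1, the smallest 3 against 3 can give, so over the 12 time points compared no adjusted p can pass). At time point 0 the shares were 8.29 ± 0.40% and 8.59 ± 0.91%.

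Few reads fell on genes, and genes of abundant complexes did not rank high as a set. The 122 members of 6 lists of abundant complexes (photosystems, phycobilisome, ATP synthase, carbon fixation and ribosome) had a median percentile of 38.7 over the 44 deep libraries, where 10000 random lists of that size gave 41.0 to 58.7. The 49 ribosomal genes (median 26.8) lay below random lists of their size, the other 5 lists did not (35.1 for photosystem II to 59.2 for ATP synthase and 68.9 for carbon fixation), and without the ribosomal genes the median was 46.0 (random lists 38.9 to 61.1). Counting on the opposite strand, which would turn each value into the antisense reads of a gene, and reads from outside genes may each lower the share. Reads from outside genes would leave the order of genes as it was. With them alone, abundant transcripts would keep a median above random lists. The median here was not above them, which argues against outside reads as the only cause if these transcripts were abundant. The files hold no measured profile to show that they were, and no count of the other strand, so opposite-strand counting stays open. No biological explanation was tested.

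The 268 background genes held a larger share in shallow control libraries. Sampling noise is argued against by genes chosen in one culture and read in another: the 311 chosen in control culture 2 held 23.9 to 64.6% of the shallow libraries of control culture 3 and 7.97 to 12.0% of its deep ones, and the 300 chosen in culture 3 held 22.5 to 51.4% and 7.46 to 9.01% in culture 2. A state shared by the control cultures at those hours is argued against by the same held-out genes at the 6 times when cultures 2 and 3 were both shallow: those chosen in culture 2 held 10.7 to 21.8% in control culture 4 and 23.9 to 64.6% in culture 3, and those chosen in culture 3 held 10.2 to 21.2% in culture 4 and 22.5 to 51.4% in culture 2; a state of single cultures was not tested. A library composition marked by multiply aligned reads stays open: across the 12 libraries of each heated culture the share and the percent of alignments that were not unique had Pearson's r of 0.0675, 0.74 and 0.87 (permutation p = 0.84, 0.0077 and 4e-04; adjusted 0.84, 0.0116 and 0.0012) and Spearman's rho of 0.30, 0.64 and 0.84 (p = 0.344, 0.0272 and 0.00116; adjusted 0.344, 0.0408 and 0.00348). Without the 2 libraries farthest from the median r was 0.74, 0.80 and 0.58, so the first value rests on those libraries and the 0.0675 decides nothing.

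Calls between the arms were more at the end than at the start but did not rise steadily: 38 at time point 3, 119 at 5, 2 at 6, 25 at 7, 196 at 8 and 532 at 11. Uneven control depth is argued against by summed deep controls, the same at each time point, against which the calls were 17 at time point 3, 261 at 5, 285 at 6, 399 at 7 and 1254 at 11. Background genes are argued against as the whole cause by the count without them, 7 at time point 3, 46 at 5, 48 at 6, 101 at 7 and 540 at 11. Drift shared by all cultures is argued against over the 984 genes called in the heated course and measured in both arms, whose median change in the heated direction was 0.99 to 1.08 on the log2 scale in the heated cultures and at most 0.0165 in the control cultures (lowest −0.0382), although genes chosen in the heated arm favour it. A response to the heating is the hypothesis that stays open, found and tested on the same data.

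The splits of the 6 libraries of a time point, 3 against 3, gave 1 of 10 as large as the real one at time points 3 (38 genes), 6 (2), 9 (241) and 11 (532), each with 0 in the highest other split, and these 10 splits are too few for a share under 0.05. With time points shuffled within each heated culture, 1 of 100 arrangements, the real one, reached its 986 genes (highest other 65). This is the smallest share that 100 arrangements can give, and it argues against unordered scatter between hours. The shuffles treat the hours of a culture as exchangeable, so they cannot tell a response to heating from a drift of these cultures. Where the real count was 0, any split reaches it and the test decides nothing: 10 of 10 at time point 0 (highest other 1) and for the lists at each of 4 time points (highest other 0), and 100 of 100 in the control cultures (highest other 27).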

How the results depend on the processing

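Fits without shallow libraries or background genes, against summed deep controls, and of heated cultures against themselves at time point 0 were chosen after the result was seen. Of 113 counts of genes under alternatives 54 stayed within 1.5 times the reported count, as did 47 of 48 counts of lists. These include fits in which the reported and the alternative count were both 0. Such fits were those of time point 0 and of the control course among the gene counts, and all 47 among the lists. Of 697 log2 values of named genes 600 kept direction and call, 93 kept direction and lost the call (38 of them genes of time point 3), and 4 turned: ssr1038 at time point 3 with summed controls (0.23), and ssr6099 (0.18), ssr1038 (0.62) and slr1978 (0.15) against time point 0. These 3 genes are background genes. Unless said otherwise the cause was not tested.

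At time point 0 leaving out a culture gave 0 to 32 genes. At time point 3 (38 genes) DESeq2's Wald test called 134, size factors 25, no filter 116, all 72 libraries 0 in edgeR and 0 in limma voom, and leaving out a culture 0 to 357. Without shallow libraries, which left control culture 4 alone, the 38 genes had a median absolute log2 of 0.88, against 2.84 in the main fit. Without background genes the count was 7, with summed controls 17 and against time point 0 4. For the change from time point 0 with culture as a replicate block it was 0. None of the 38 genes was among the 17 or the 4. With summed controls 23 of the 38 kept their direction, with a median absolute log2 of 0.14 over the 38, and against time point 0 11 did. At time point 6 (2 genes) these gave 44 (Wald), 30 (no filter), 17 and 10 (72 libraries), 0 to 112 (a culture left out), 112 (no shallow libraries), 48 (no background genes), 285 (summed controls) and 122 (against time point 0). At time point 9 (241) they gave 20 (Wald), 140 and 135 (72 libraries), 69 to 525 (a culture left out), 525 (no shallow libraries), 398 (no background genes), 944 (summed controls), 694 (against time point 0) and 18 (change from time point 0, replicate block). At time point 11 (532) they gave 274 to 577 (a culture left out), 1254 (summed controls) and 232 (change from time point 0, replicate block); without shallow libraries control culture 4 alone stood against 2 heated ones, with 509.

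The trajectory test (167) gave 439 by DESeq2's likelihood ratio test, 281 without background genes, 33 to 484 with a culture left out and 23 from slopes per culture in limma. The heated course (986) gave 475 to 873 with a culture left out. For lists at time point 11 fry called 2 where camera called 0.

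The label number as a replicate block gave 172 genes at time point 3, 0 at 6, 0 at 9 and 170 at 11, and changed no call of a list. Only numbers 2 and 3 occur in both arms, and libraries that share one had correlations of their deviations from −0.12 to 0.18, so they share only a number. Depth limited the genes that could be tested, since the filter works on counts: 843 passed it at time point 5, where 4 of the 6 libraries were shallow, and 2731 at time point 0.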

Other observations

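The counts by replicon were made after the result was seen, and no test of a difference between replicons was run.

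Genes of the large plasmids, told by the numbering convention of their locus tags, changed in both directions as the cultures warmed. In the heated cultures 18 of 90 genes of pSYSM were higher and 9 lower at time point 11 than at 0, 11 and 3 of 49 of pSYSX, 10 and 15 of 84 of pSYSA, and 7 and 7 of 38 of pSYSG (edgeR's quasi-likelihood test over all genes, adjusted p under 0.05). Between the arms at time point 11, 8 of 33 pSYSM genes were higher and 4 lower, 3 and 1 of 25 on pSYSX, 5 and 6 of 40 on pSYSA, and 2 and 4 of 24 on pSYSG, beside 251 and 248 of 1923 other genes. Among them were sll8025 of pSYSG (log2 3.22, SE 0.36) and the background gene slr7068 of pSYSA (−4.19, SE 0.42).

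Among the sigma factor genes, which set the promoters that RNA polymerase reads, 2 of 9 were higher and none lower within the heated cultures at time point 11 than at 0. Between the arms at time point 11 only 5 of the 9 had enough counts to be tested, of which none was higher and rpoD was lower (log2 −1.24). Of 14 nitrogen genes 5 were higher and 4 lower within the heated cultures, against 2 and 2 of 12 between the arms, and of 4 fatty acid desaturase genes 3 were higher, against 2 of 3 between the arms.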
